A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

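RNA from 8 liquid cultures of the cyanobacterium Synechocystis was sequenced: 3 of the wild type (WT), 3 of a strain overexpressing wild-type RNase E, called rne(WT), and 2 of a strain overexpressing an RNase E that cannot sense the 5' end of its substrate, called rne(5p). RNase E is the endoribonuclease that starts much of the RNA decay and processing in many bacteria. Per the labels, the cultures were separate biological replicates, grown at 30 °C in BG-11 medium with 0.3% thiosulphate and 10 mM TES at pH 8.0, shaken at 135 rpm under 30 µmol photons of white light, and 20 ml was taken from each.

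The libraries were made by tagRNA-seq, per the labels' protocols. Ribosomal RNA was depleted with a service provider's own probes. RNA ends with a 5' monophosphate, as processing leaves them, received one tag. The monophosphorylated RNA that was left was digested, triphosphate ends were converted to monophosphates and these ends, as transcription start sites have them, received another tag. Reads with the first tag give processing sites (PSS) and reads with the second give transcription start sites (TSS).

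The authors deposited 3 tables of normalized read counts, a signal that is never negative, for 6134 transcript features (protein-coding genes, untranslated regions, antisense and other non-coding RNAs), 4440 TSS and 6490 PSS, and a list of the site positions. The submitters' processing notes name bcl2fastq, cutadapt, Bowtie2, HTSeq, bedtools and DESeq2 1.30.1, without their roles, and the position list was written with rtracklayer 1.50.0, per the file headers. How sites were called, how reads on overlapping features were assigned, whether counting used the strand, and the genome build are not given in the sources used here, so values of antisense and overlapping features are uncertain to that extent. Each deposited column is a whole multiple of its smallest step (tolerance 0.01 of a read; 100% of values whole), so read counts and the factor of each library could be recovered. The factors differ between the 3 tables, which the authors therefore scaled separately, and every test of single features, sites and lists stays within a table. Comparisons of PSS with TSS or with a transcript, used only in weighing explanations, cross tables. The recovered depth was 4908458 to 6500669 reads per library on transcript features, 456231 to 917667 on TSS and 35774 to 66049 on PSS. PCR copies are counted in these numbers.

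The column headings dWT and TV are not explained in the sources used here. The 3 dWT columns were taken as rne(WT) and the 2 TV columns as rne(5p), from the number of replicates and the likeness of TV to the short name of the rne(5p) samples, and the levels of rne, which are near equal in both strains, do not test this. No 2 libraries were alike within sampling noise, so all 8 were kept. Groups of 3 or fewer are too small for a test of single outlying libraries.

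Values were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3), with a trend in the variance prior. Features with a mean of at least 10 over the 8 libraries entered: 4668 transcript features, 3985 TSS and 972 PSS. All 8 libraries entered 1 fit with the 3 strains as groups, and the 3 comparisons were two-sided contrasts. P values were adjusted by the Benjamini-Hochberg method within each table and comparison, a feature was called at an adjusted p below 0.05, and every adjusted p of a feature or site in the text comes from this test. Fold changes are on the log2(value + 1) scale and understate the change of features with low values. The median standard error of a log2 fold change was 0.204 for transcript features in rne(WT) against WT and 0.228 in both comparisons with rne(5p). It was 0.299 and 0.335 for TSS, and 0.458 and 0.512 for PSS. Tested on simulated reads for 4666 transcript features of the rne(WT) and WT comparison, the procedure recovered 97% of features changed 4-fold and 71.7% of those changed 2-fold. For 957 PSS of the same comparison the shares were 87.8% and 27.7%, and for 978 PSS of the comparison of both overexpressing strains 80.2% and 17.8%. Wrong calls made up from 4% (TSS) to 8.42% (PSS) of the simulated calls, both in rne(5p) against WT, so their share can exceed the threshold of 0.05.

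Gene lists were tested with camera (limma, preset correlation 0.01, protein-coding features only, Benjamini-Hochberg over the lists of a comparison) and again with an estimated correlation. Of 27 lists fixed beforehand, 24 matched the locus tags of the table and 23 were given a set test: RNases with RNA helicase and RNA-binding proteins, photosystem I, photosystem II, phycobilisome, cytochrome b6f, ATP synthase, NDH-1, Rubisco and carboxysome, low-carbon uptake, nitrogen assimilation, chlorophyll synthesis, chaperones, high-light inducible proteins, iron, phosphate, sigma factors, pili, CRISPR-Cas, hydrogenase and the plasmids pSYSA, pSYSM, pSYSX and pSYSG. The rne operon, with 2 genes, is given as values. The lists of ribosomal proteins, small RNAs and tRNA genes were written as gene symbols, which matched no tag, and were not run. The tables pair no locus tag with a symbol and none of the 6134 feature names matched the gene table used here, which is of another substrain, so functions given beside a tag are general background.

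The tests, samples, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule takes, per comparison, the 12 highest and 12 lowest fold changes among called features whose libraries do not overlap, with 1 feature per gene, the genes rne, rnhB, psbA2, psbA3, pnp, rnj, crhR and pilA1 whatever their values, 3 called members of each list past its test, and the 5 highest and 5 lowest called sites. Other called list members, the CRISPR arrays and the clusters of sites were added after their values were seen.

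The alternatives were pseudocounts of 0.5 and 5, no filter or a minimum mean of 50, a fold threshold of 2, scaling by library totals or by TMM, the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on the recovered reads, no variance trend, only the strains compared, the replicate number as a block, and leaving out each library. The edgeR test called 164 transcript features in rne(WT) against WT, 13 in rne(5p) against rne(WT) and 582 in rne(5p) against WT. It called 219, 27 and 494 TSS and 87, 284 and 366 PSS. With no genome that fits the coordinates at hand, the base composition around PSS and the change of PSS against that of the transcript holding them were not run, and sites are given by replicon, position and strand with no gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.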

Results

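Transcript levels, transcription start sites and processing sites were measured in WT (n = 3), rne(WT) (n = 3) and rne(5p) (n = 2) cultures grown under 1 condition. Values are the deposited normalized read counts, given as mean ± SD over the libraries of a strain. The libraries held 4908458 to 6500669 reads on transcript features. The 10 most abundant features took 50.9 to 53.8% of the transcript table in WT, 44.4 to 47.9% in rne(WT) and 40.1 to 41.3% in rne(5p). On the first principal component of the transcripts, which held 41.3% of the variance, both rne(5p) libraries lay at 22.7 and 24.0, the rne(WT) libraries between -5.56 and 7.40 and the WT libraries between -28.8 and -7.94. WT replicate 3 stood apart from the other WT libraries on the second component, at -19.0 against 17.1 and 19.5, so counts without it are given beside those from all libraries.

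The comparison of rne(WT) with WT asks what differs in the strain that overexpresses wild-type RNase E. WT was the only strain without overexpression, so effects of RNase E and of strain construction cannot be told apart. Transcripts of slr1129, which is rne, rose from 672 ± 79.0 to 4711 ± 367, or 7.01-fold (n = 3 each). In rne(5p) slr1129 stood at 4566 ± 273 (n = 2). The neighbouring gene slr1130, which is rnhB and encodes ribonuclease HII, rose from 98.9 ± 22.3 to 755 ± 151, or 7.58-fold. With limma and Benjamini-Hochberg adjustment, adjusted p was 1.2e-06 for slr1129 and 2.95e-05 for slr1130. Both genes rose in both overexpressing strains, so effects of RNase E and of ribonuclease HII cannot be told apart in comparisons with WT. The table lists rne under 1 tag, so reads of the introduced copy and of any native copy are counted together. The short name of the rne(WT) samples, Drne, may stand for a deletion of rne. Whether a native copy remains in the overexpressing strains was not tested.

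The CRISPR3 array of plasmid pSYSA, a source of guide RNAs in the defence against foreign DNA, rose 5.37-fold, from 7565 ± 2316 to 39891 ± 8897 (limma with Benjamini-Hochberg, adjusted p = 0.000921). CRISPR1 rose 2.77-fold, from 1130 ± 452 to 2958 ± 314 (limma, Benjamini-Hochberg adjusted p = 0.0117), a call lost without rne(WT) replicate 3 (adjusted p = 0.0580). CRISPR2 was measured at 141 ± 48.6 in WT and 331 ± 157 in rne(WT), with a limma adjusted p, by Benjamini-Hochberg, of 0.0932, which passed with DESeq2 (0.0124) and with scaling by library totals (0.0242). The pSYSA genes slr7096, slr7097, slr7098 and slr7099 rose between 5.63-fold and 8.31-fold, slr7097 from 154 ± 7.22 to 1016 ± 105. Of 49 tested pSYSA genes 25 rose and 0 fell, 35 and 0 when adjusted over the list alone, with a median fold change of 2.06. The list passed limma's camera test (Benjamini-Hochberg adjusted p = 2.36e-31), with an adjusted p = 0.0685 with an estimated correlation.

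On plasmid pSYSM 11 of 50 tested genes rose and 0 fell, 23 and 0 when adjusted over the list alone, with a median fold change of 1.44. Camera gave a Benjamini-Hochberg adjusted p = 4.73e-16, and an adjusted p = 0.123 with an estimated correlation. Among them slr5053 rose 5.84-fold, from 54.7 ± 44.8 to 262 ± 52.5, and slr5102 rose 3.15-fold, from 53.4 ± 27.9 to 160 ± 40.5. Their calls were lost without WT replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0762 for both), without rne(WT) replicate 2 (0.0797 and 0.0896) and without rne(WT) replicate 3 (0.0769 and 0.0677), and that of slr5053 also without a variance trend (0.0543). The plasmids pSYSX, with 13 tested genes, and pSYSG, with 15, had no called member and gave camera adjusted p, by Benjamini-Hochberg, of 0.397 and 0.300. On each of the 4 plasmids nearly all genes of one strand were listed at 0 in every library (78 of 79 on pSYSM, 88 of 89 on pSYSX, 50 of 51 on pSYSA and 31 of 32 on pSYSG), so the plasmid lists rest mostly on the other strand.

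Nitrogen assimilation genes split into 2 members that rose and 6 that fell of 17, or 3 and 10 when adjusted over the list alone. The risers were ssl1911 and sll1515, which encode the factors that inactivate glutamine synthetase. ssl1911 rose 4.03-fold, from 3163 ± 1154 to 12262 ± 1358, and sll1515 rose 3.56-fold, from 897 ± 130 to 3237 ± 787. ssl0707, which encodes the signalling protein PII, fell from 4337 ± 149 to 2268 ± 261, slr0898, the nitrite reductase gene, from 1632 ± 338 to 779 ± 133, and sll1451, a nitrate transporter gene, from 561 ± 60.3 to 293 ± 47.2. By limma with Benjamini-Hochberg adjustment, adjusted p was 0.00235 for ssl0707, 0.0119 for slr0898 and 0.0110 for sll1451. The call on slr0898 was lost without rne(WT) replicate 3 (0.0624) and that on sll1451 without WT replicate 2 (0.0573) or rne(WT) replicate 3 (0.0650). The list had a median log2 fold change of -0.61 and a mean of -0.26, and passed camera (Benjamini-Hochberg adjusted p = 0.000794), with an adjusted p = 0.25 with an estimated correlation.

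Genes of the bidirectional hydrogenase had a median log2 fold change of -0.63. Of 5 members 2 fell and 0 rose, 4 and 0 when adjusted over the list alone. sll1223 fell from 270 ± 23.9 to 153 ± 41.1 and sll1226 from 401 ± 25.8 to 258 ± 17.1. Camera gave a Benjamini-Hochberg adjusted p = 0.000466, and an adjusted p = 0.361 with an estimated correlation. In limma with Benjamini-Hochberg adjustment both single calls were lost with scaling by library totals (adjusted p = 0.0968 and 0.115). They were also lost without WT replicate 1 (0.0756 and 0.0662), WT replicate 2 (0.140 and 0.111), rne(WT) replicate 2 (0.164 and 0.107), rne(WT) replicate 3 (0.154 and 0.0720), rne(5p) replicate 1 (0.0911 and 0.0613) or rne(5p) replicate 2 (0.0914 and 0.0627), and that of sll1226 without rne(WT) replicate 1 (0.0673).

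Of 12 photosystem I genes none was called by limma, over all genes or when adjusted over the list alone, while the list as a whole was lower, with a median log2 fold change of -0.40. Camera gave a Benjamini-Hochberg adjusted p = 0.000794, and an adjusted p = 0.504 with an estimated correlation. Outside these lists, slr1452, which encodes a sulfate-binding protein, rose 5.13-fold, from 39.2 ± 15.0 to 198 ± 31.8. slr0884, the glyceraldehyde-3-phosphate dehydrogenase gene gap1, fell from 634 ± 130 to 184 ± 35.2. sll0247, the iron-stress chlorophyll-protein gene isiA, fell from 415 ± 19.6 to 225 ± 26.7, and sll1689, which encodes the sigma factor SigE, from 1894 ± 135 to 928 ± 185. With limma and Benjamini-Hochberg adjustment, adjusted p was 0.000921 for slr1452 and slr0884, 0.00683 for sll0247 and 0.00559 for sll1689. Of features with no function given here, ncl0020 rose 19.2-fold, from 50 ± 8.30 to 981 ± 181, ncr0020 rose 6.08-fold, from 921 ± 109 to 5590 ± 404, and sll1305 fell from 236 ± 42.7 to 72.3 ± 18.2.

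In all, 89 transcript features rose and 83 fell of 4668 tested, and 57 and 29 of these changed at least 2-fold. The counts included 79 and 73 protein-coding genes, 3 and 3 antisense RNAs and 2 and 5 other non-coding RNAs. With scaling by library totals, which moved the median log2 fold change of all features from 0.00 to 0.24, the counts were 271 and 44. The number of calls, 172 from all libraries, was 87 without WT replicate 2, 347 without WT replicate 3, 92 without rne(WT) replicate 2, 70 without rne(WT) replicate 3, and 104 without rne(5p) replicate 1 or rne(5p) replicate 2. Of the genes chosen for any value, limma with Benjamini-Hochberg adjustment called none of psbA2 (slr1311, log2 fold change 0.29), psbA3 (sll1867, 0.22), pnp (sll1043, -0.24), rnj (slr0551, 0.42), crhR (slr0083, -0.08) and pilA1 (sll1694, -0.32). Their lowest adjusted p was 0.0631, for slr0551, which passed with a minimum mean of 50 (0.0481), with scaling by library totals (0.0106) and with DESeq2 (0.00186). psbA2 and psbA3 are nearly identical in sequence, so their reads could not be assigned with certainty.

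The remaining lists did not pass camera, with Benjamini-Hochberg adjusted p of 0.0559 for RNases, RNA helicase and RNA-binding proteins, 0.270 for photosystem II, 0.868 for the phycobilisome, 0.648 for cytochrome b6f and 0.409 for ATP synthase. The values were 0.911 for NDH-1, 0.868 for Rubisco and carboxysome, 0.533 for low-carbon uptake, 0.868 for chlorophyll synthesis, 0.440 for chaperones and 0.918 for high-light inducible proteins. They were 0.451 for iron, 0.409 for phosphate and for sigma factors, 0.868 for pili and 0.259 for CRISPR-Cas, of which 6 genes were tested. Among these lists the RNases held 2 genes that rose, both of the rne operon, and 3 when adjusted over the list alone. The RNases had a median log2 fold change of 0.04 and a mean of 0.45, and the list was not tested without the rne operon. The low-carbon list held 1 that rose (3 when adjusted over the list alone), and photosystem II, chaperones, iron and sigma factors 1 each that fell (2, 1, 1 and 1 when adjusted over the list alone, where 1 iron gene also rose and 1 NDH-1 gene fell). The RNase list passed without WT replicate 3 (0.00771) or rne(WT) replicate 3 (0.0427), photosystem II without WT replicate 3 (0.0436) and plasmid pSYSX without WT replicate 1 (0.0469).

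**Figure D1:**
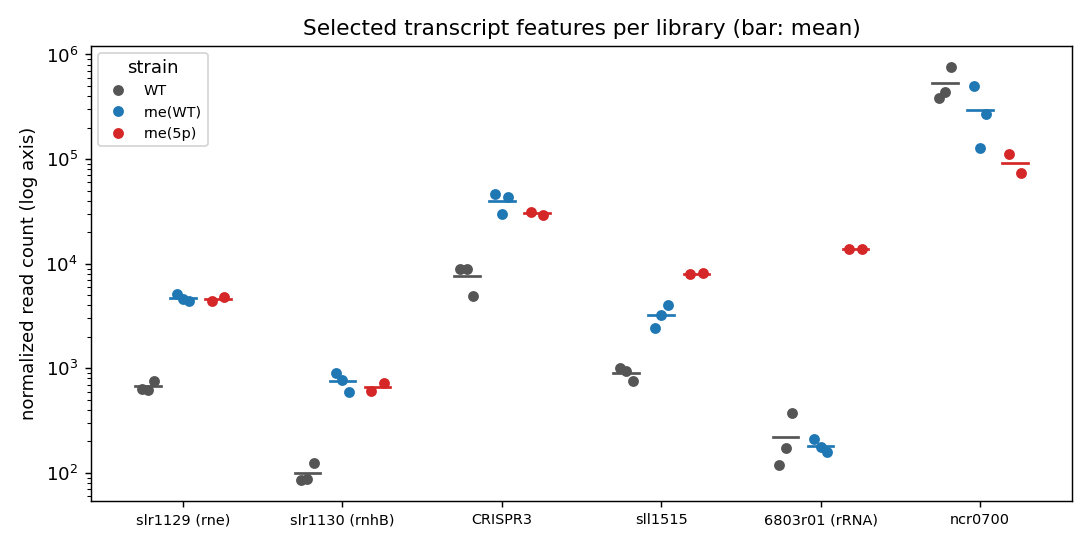
Normalized read counts (log axis) of 6 transcript features in each library of WT, rne(WT) and rne(5p), with a bar at each mean. For slr1129 the WT libraries lie between 624 and 764 and those of both overexpressing strains between 4373 and 5118, while 6803r01 averages 13843 in rne(5p), 182 in rne(WT) and 222 in WT.

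At transcription start sites the same comparison gave 96 sites that rose and 96 that fell of 3985 tested. Of 87 tested TSS on pSYSA 38 rose and 0 fell, and 83 had a log2 fold change above 0, with a median fold change of 2.12. On pSYSM 8 of 91 rose, and on the chromosome 49 rose and 96 fell of 3745. The pSYSA sites at 94217 and 94696 on the plus strand rose from 10.8 ± 4.0 to 94.7 ± 13.5 and from 18.0 ± 2.69 to 148 ± 23.6 (n = 3 each). The chromosomal sites at 1147017 on the plus strand and 1116114 on the minus strand fell from 182 ± 55.1 to 28.9 ± 9.44 and from 181 ± 24.2 to 35.4 ± 7.31. By limma with Benjamini-Hochberg adjustment, adjusted p was 3.96e-05, 4.61e-06, 9.05e-05 and 3.96e-05 for these 4 sites. With scaling by library totals, which moved the median of all TSS from 0.01 to 0.22, 168 rose and 47 fell. The number of calls, 192 from all libraries, was 111 without WT replicate 2, 96 without rne(WT) replicate 2 and 89 without rne(WT) replicate 3, and 249 without WT replicate 3.

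Processing sites rose at 62 positions and fell at 20 of 972 tested. Of the risers 39 lay on pSYSA, all on the plus strand between 90108 and 92560, where 40 sites were tested, with a median fold change of 10.3. Sites low in WT passed the minimum mean because they were high in the overexpressing strains, so the filter partly set this share and median. The site at 91410 rose from 7.94 ± 2.03 to 374 ± 137 and that at 91216 from 8.21 ± 2.22 to 264 ± 56.1 (limma, Benjamini-Hochberg adjusted p = 1.11e-10 for both). Summed over the 118 sites listed in this stretch, the signal was 212 to 311 in the WT libraries, 2865 to 3618 in rne(WT) and 2394 and 3002 in rne(5p). On the chromosome 23 sites rose and 20 fell of 914, among them the site at 3181791 on the minus strand, from 54.0 ± 10.5 to 16.8 ± 9.42 (limma, Benjamini-Hochberg adjusted p = 0.00768), a call lost without rne(WT) replicate 2 (0.0538). Without WT replicate 3 the calls numbered 80, and with scaling by library totals, which moved the median of all PSS from -0.02 to -0.10, 57 rose and 28 fell. With no filter on the mean 98 rose and 9 fell.

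**Figure D2:**
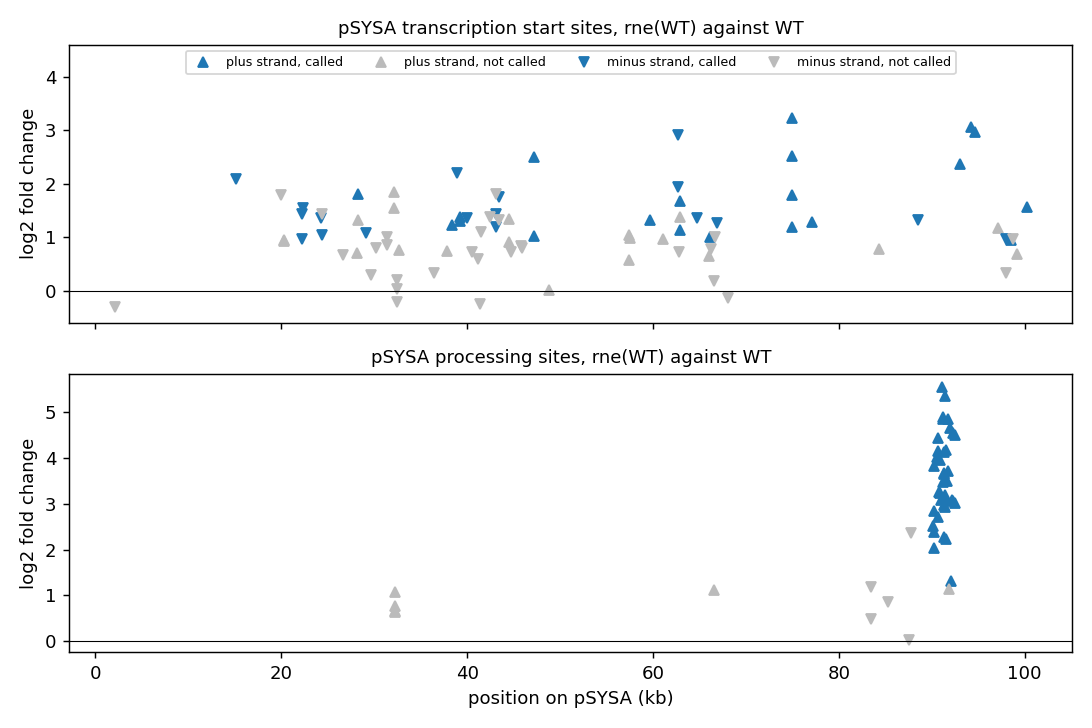
Log2 fold change of rne(WT) against WT at each tested site along pSYSA (position in kb), with TSS above and processing sites below, triangles pointing up for the plus and down for the minus strand, and called sites in blue. Of 87 TSS 83 lie above 0, and the 39 called processing sites lie between 90108 and 92560 on the plus strand.

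The comparison of rne(5p) with rne(WT) asks what differs between the strains that overexpress the 5'-sensing-deficient and the wild-type enzyme. The enzyme changes together with the strain. Its effects therefore cannot be told apart from those of strain construction or of any difference in library preparation. slr1129 stood at 4566 ± 273 in rne(5p) (n = 2) and 4711 ± 367 in rne(WT) (n = 3), a log2 difference of -0.04 with a limma adjusted p, by Benjamini-Hochberg, of 0.912. Processing sites changed at 265 of 972 tested positions, 143 higher and 122 lower in rne(5p). The site at 2589111 on the minus strand of the chromosome rose from 23.1 ± 22.4 to 1205 ± 102 and that at 2781050 on the plus strand from 10.3 ± 8.97 to 292 ± 17.3. The sites at 959937 and 2613286 on the plus strand fell from 245 ± 27.6 to 12.3 ± 1.39 and from 284 ± 8.90 to 16.4 ± 1.47. By limma with Benjamini-Hochberg adjustment, adjusted p was 8.45e-09, 9.31e-07, 2.70e-09 and 2.48e-09 for these 4 sites.

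Grouped by gaps of at most 200 nt, the called sites formed 118 clusters, single sites included, of which 23 held both directions, and closeness was not tested against chance. Between 2376891 and 2377461 on the plus strand 8 called sites were higher and 9 lower in rne(5p), and between 959778 and 959952 there were 11 and 5. Between 726456 and 726850 on the minus strand 1 was higher and 9 were lower. Others held 1 direction only, with 7 higher between 810898 and 811017 on the minus strand and 7 lower between 943547 and 943804 on the plus strand. In the stretch of pSYSA from 90108 to 92560 limma called 0 of 40 sites between the overexpressing strains, with a median log2 difference of -0.40. The site at 2961377 on the plus strand was listed at 0 in both rne(5p) libraries and at 24.6 ± 17.5 in rne(WT). The number of called PSS was 130 without rne(5p) replicate 1, 114 without rne(5p) replicate 2 and 321 without WT replicate 3. With scaling by library totals, which moved the median log2 difference from 0.10 to -0.02, 119 PSS were higher and 135 lower, so which direction holds more sites depends on the scaling.

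**Figure D3:**
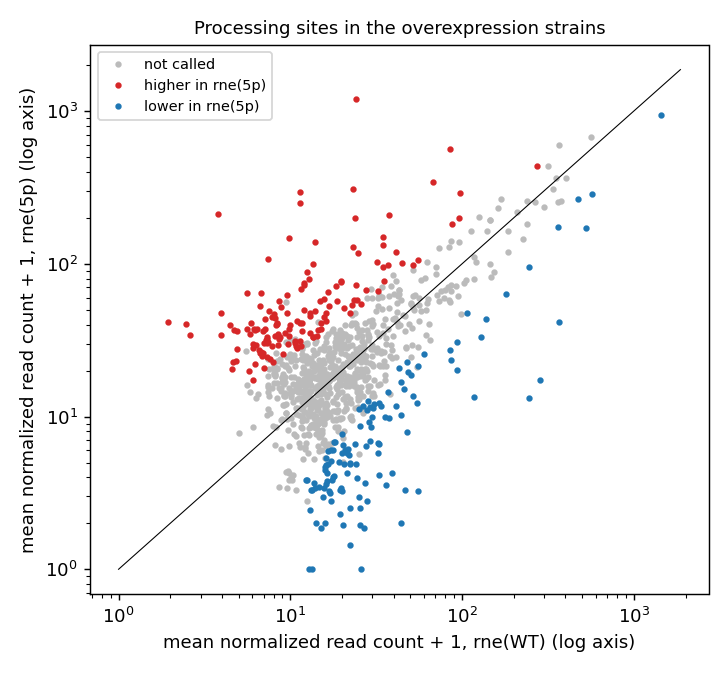
Mean normalized read count plus 1 of each tested processing site in rne(5p) against rne(WT), both on log axes, with a line of equality. Of 972 sites, 143 are higher (red) and 122 lower (blue) in rne(5p), and the highest red point is the site at 1205 in rne(5p) and 23.1 in rne(WT).

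Among transcripts, 8 features were higher and 4 lower in rne(5p) than in rne(WT) of 4668 tested, where 582 had an unadjusted p below 0.05. Among them were both tested ribosomal RNA features. 6803r01, with the largest difference, rose 76.1-fold, from 182 ± 26.8 to 13843 ± 80.4, and 6803r06 rose 41.4-fold, from 105 ± 14.0 to 4360 ± 187 (limma, Benjamini-Hochberg adjusted p = 3.95e-05 and 4.80e-05). In WT they stood at 222 ± 134 and 125 ± 73.2. The 6 rRNA features took 0.374 and 0.349% of the reads of the rne(5p) libraries and 0.00308 to 0.00942% in the other 6. Of 36 tRNA features none was called by limma between these strains.

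The other 10 calls had adjusted p from 0.00180 to 0.0460 by limma with Benjamini-Hochberg adjustment. The non-coding RNAs ncr1230 and ncl1700 rose from 3.53 ± 2.44 to 224 ± 15.8 and from 5.19 ± 2.65 to 117 ± 3.65. Both calls were lost without rne(5p) replicate 1 (0.105 and 0.124) or rne(5p) replicate 2 (0.0857 and 0.111). sll1515 rose a further 2.53-fold, from 3237 ± 787 to 8040 ± 193, and sll0057, the gene of the chaperone cofactor GrpE, rose 2.39-fold, from 812 ± 124 to 1927 ± 81.9, where WT had 1752 ± 408. Antisense RNAs to infB and isiA, slr0744-as2 and sll0247-as2, fell from 196 ± 25.9 to 64.9 ± 8.83 and from 3104 ± 547 to 1090 ± 165. The calls on sll1515, sll0057, slr0744-as2 and sll0247-as2 were lost without rne(WT) replicate 1 (0.0702, 0.120, 0.0826 and 0.112), rne(WT) replicate 2 (0.104, 0.0630, 0.104 and 0.0630), rne(5p) replicate 1 (0.440, 0.474, 0.320 and 0.330) or rne(5p) replicate 2 (0.462, 0.493, 0.479 and 0.493). Those on the last 3 were lost without rne(WT) replicate 3 (0.144 each), and those on sll1515, sll0057 and sll0247-as2 without WT replicate 2 (0.0769, 0.0813 and 0.0769). The count of 12 became 20 without WT replicate 1, 6 without WT replicate 2, 97 without WT replicate 3, 4 without rne(WT) replicate 1, 6 without rne(WT) replicate 2 or 3, and 2 without either rne(5p) library. With scaling by library totals, which moved the median log2 difference from 0.00 to 0.13, 15 were higher and 2 lower.

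Of 23 gene lists 2 passed the set test between the overexpressing strains. pSYSA genes were lower in rne(5p), with a median log2 difference of -0.24 and 0 of 49 called by limma, over all genes or when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00268). pSYSM genes were higher, with a median of 0.17 and 1 of 50 called, 4 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0327). Both lists had an adjusted p = 0.643 with an estimated correlation, and that of pSYSM was also lost without rne(WT) replicate 2 (0.0958) or rne(5p) replicate 1 (0.0540). The other 21 lists had camera adjusted p, by Benjamini-Hochberg, from 0.0769 for NDH-1 to 0.95 for the RNases. High-light inducible proteins had a median log2 difference of 1.08 with 0 of 4 called by limma over all genes and 3 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.170). Over all genes 1 chaperone gene and 1 nitrogen gene were higher and no other member of these lists was called by limma. Adjusted over the list alone, 4 chaperone genes, 2 RNase genes, 2 nitrogen genes and 1 each of cytochrome b6f, ATP synthase, sigma factors and pili were higher, and 3 photosystem II genes and 1 each of photosystem I, phycobilisome and chlorophyll synthesis lower. Of these lists, ATP synthase (0.00681) and Rubisco and carboxysome (0.00681) passed without rne(WT) replicate 1, and photosystem I (0.0126), phycobilisome (0.0093), chlorophyll and tetrapyrrole synthesis (0.0227) and high-light inducible proteins (0.0126) without rne(WT) replicate 2. NDH-1 complex (0.00149), Rubisco and carboxysome (0.0282) and low-carbon inducible uptake (0.00222) passed without rne(5p) replicate 1, and ATP synthase (0.0282) without rne(5p) replicate 2. At TSS 8 sites were higher and 3 lower, all on the chromosome. The site at 1518035 on the plus strand stood at 10659 ± 1999 in WT, 3926 ± 85.7 in rne(WT) and 1494 ± 88.6 in rne(5p), and fell between both overexpressing strains by 1.39 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0146), a call lost without rne(WT) replicate 2 (0.0635), rne(5p) replicate 1 (0.223) or rne(5p) replicate 2 (0.241). Without WT replicate 3 the count of 11 TSS became 60, without rne(WT) replicate 1 it became 3, without rne(WT) replicate 3 it became 7, and limma called 0 without rne(WT) replicate 2, rne(5p) replicate 1 or rne(5p) replicate 2, with 436, 260 and 254 sites at an unadjusted p below 0.05. From all libraries edgeR called 27 and DESeq2 47 TSS.

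The comparison of rne(5p) with WT asks what differs in the strain that overexpresses the 5'-sensing-deficient enzyme. slr1129 rose 6.81-fold and slr1130 rose 6.72-fold, to 662 ± 78.4 (limma, Benjamini-Hochberg adjusted p = 5.04e-06 and 8.83e-05). The inactivating factors of glutamine synthetase rose further than any other nitrogen gene, sll1515 9.02-fold to 8040 ± 193 and ssl1911 5.94-fold to 18001 ± 952 (n = 2). slr1452 rose 8.94-fold to 344 ± 42.6. CRISPR3 rose 4.15-fold to 30261 ± 1748. slr0551, which is rnj and encodes RNase J, rose from 2260 ± 63.8 to 4214 ± 215. With limma and Benjamini-Hochberg adjustment, adjusted p was 1.50e-05 for sll1515, 0.000369 for ssl1911, 0.000219 for slr1452, 0.00189 for CRISPR3 and 0.00149 for slr0551. The fold change of slr0551 did not differ between the overexpressing strains by limma with Benjamini-Hochberg adjustment (adjusted p = 0.154), though DESeq2 called it (0.00275).

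Of the pSYSM genes 22 of 50 rose and 0 fell, 25 and 0 when adjusted over the list alone, with slr5053 up 24.6-fold to 1132 ± 422 and slr5102 up 6.46-fold to 325 ± 48.5. Of the pSYSA genes 19 of 49 rose and 0 fell, 20 and 0 when adjusted over the list alone. Camera gave Benjamini-Hochberg adjusted p of 2.02e-11 and 9.87e-10, and an adjusted p = 0.383 with an estimated correlation for both. Photosystem I genes had a median log2 fold change of -0.41, with 4 of 12 lower, also when adjusted over the list alone. ssr0390, which is psaK1, fell from 3030 ± 21.8 to 1311 ± 90 and ssr2831, which is psaE, from 12790 ± 1554 to 6474 ± 64.3. With limma and Benjamini-Hochberg adjustment, adjusted p was 0.00189 for ssr0390 and 0.00684 for ssr2831, and the call on ssr2831 was lost without rne(5p) replicate 1 (0.0760) or rne(5p) replicate 2 (0.0813). Of the hydrogenase genes 2 of 5 fell, 4 when adjusted over the list alone. Camera gave Benjamini-Hochberg adjusted p of 0.00349 for photosystem I and 0.00592 for the hydrogenase, and an adjusted p = 0.655 with an estimated correlation for both.

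Nitrogen assimilation held 2 genes that rose and 6 that fell of 17, also when adjusted over the list alone. slr0288, a glutamine synthetase gene (glnN), fell from 1605 ± 144 to 782 ± 2.08, slr0898 from 1632 ± 338 to 559 ± 111 and ssl0707 from 4337 ± 149 to 2381 ± 19.3. Adjusted p by limma with Benjamini-Hochberg adjustment was 0.00348 for slr0288, 0.00173 for slr0898 and 0.00321 for ssl0707, which without rne(5p) replicate 1 had 0.05005. The list gave a camera Benjamini-Hochberg adjusted p = 0.0647 and passed without WT replicate 3 (0.0171), rne(WT) replicate 1 (0.0495), rne(WT) replicate 2 (0.0428) or rne(5p) replicate 2 (0.0274). Its adjusted p = 0.655 with an estimated correlation.

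Of 740 antisense RNAs 7 rose and 39 fell, of 247 other non-coding RNAs 8 rose and 30 fell, and of 3276 protein-coding genes 258 rose and 188 fell. The difference between these classes was not tested, and the balance of all features depends on the scaling. The small RNA ncr0700, known as PmgR1, was the highest of the features drawn per library and fell from 529177 ± 207129 to 92660 ± 26200 (limma, Benjamini-Hochberg adjusted p = 0.0194), a call lost without WT replicate 2 (0.0509), rne(5p) replicate 1 (0.0966) or rne(5p) replicate 2 (0.175). sll0247-as2 fell from 5303 ± 1420 to 1090 ± 165 (limma, Benjamini-Hochberg adjusted p = 0.000407), as did its sense gene sll0247, from 415 ± 19.6 to 187 ± 10.7. The antisense RNA slr1596-as rose 8.79-fold, from 32.3 ± 6.42 to 288 ± 14.7. In the same libraries rRNA features took 0.349 and 0.374% of reads.

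The remaining lists had camera Benjamini-Hochberg adjusted p of 0.215 for RNases, RNA helicase and RNA-binding proteins, 0.135 for photosystem II, 0.303 for the phycobilisome and NDH-1, 0.946 for cytochrome b6f and 0.6 for ATP synthase. They were 0.282 for Rubisco and carboxysome, 0.402 for low-carbon uptake and chlorophyll synthesis, 0.873 for chaperones, 0.350 for high-light inducible proteins, 0.915 for iron and 0.949 for phosphate and pSYSG. They were 0.703 for sigma factors, 0.552 for pili, 0.695 for CRISPR-Cas and 0.375 for pSYSX. The RNase list includes slr1129 and slr1130, both higher in this strain, and was not tested without them. Without WT replicate 3 the RNases (0.0452) and photosystem II (0.0276) passed, without rne(5p) replicate 2 photosystem II (0.0238), and without rne(5p) replicate 1 low-carbon inducible uptake (0.0194).

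In all, 286 transcript features rose and 283 fell in rne(5p) against WT, and 140 and 131 changed at least 2-fold. Of TSS 199 rose and 260 fell of 3985, and of PSS 210 rose and 155 fell of 972. The TSS at 1518035 fell by 2.82 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 1.38e-06) and the pSYSM TSS at 52510 on the plus strand rose from 22.6 ± 20.6 to 656 ± 256 (0.000151). All 40 tested pSYSA PSS between 90108 and 92560 rose, with a median fold change of 8.54. Of 118 listed sites there only 40 were tested. Sites low in WT passed the minimum mean because they were high in the overexpressing strains, so the filter partly set this share and median. With scaling by library totals 1127 transcript features rose and 120 fell, and 405 and 141 TSS, while the median log2 fold changes moved from 0.00 to 0.37 and from 0.03 to 0.25. For PSS this scaling turned the balance, to 170 that rose and 183 that fell, and moved the median from 0.12 to -0.08. The number of transcript calls, 569 from all libraries, was 299 without WT replicate 2, 764 without WT replicate 3, 113 without rne(5p) replicate 1 and 126 without rne(5p) replicate 2. Without rne(5p) replicate 1 and rne(5p) replicate 2, TSS calls numbered 103 and 108, against 459 from all libraries, and PSS calls 186 and 170, against 365. Without WT replicate 3 they numbered 474 and 326.

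Calls against WT overlapped between the overexpressing strains. Of transcript features 78 rose and 68 fell in both, against 5.45 and 5.03 for independent lists, and 0 moved in opposite directions by limma. In 100 simulations of unchanged strains with shared controls the mean overlaps were 0 and 0.01. Unchanged strains give almost no calls by construction, so these means do not show what shared controls add to lists of this length. Of TSS 68 rose and 72 fell in both, against 4.79 and 6.26, with 0 opposite. Of PSS 60 rose in both, against 13.4, and 5 fell in both, against 3.19, while the site at 2613286 rose in rne(WT) and fell in rne(5p). Among the 60 shared risers, 39 lay in the pSYSA stretch from 90108 to 92560. Neighbouring sites are not independent, so 13.4 is no fair measure of chance for them. The covariance of log2 fold changes was 0.184 for transcripts, 0.305 for TSS and 0.807 for PSS, and 0.0339, 0.0569 and 0.114 in the simulations, a difference of 0.150, 0.248 and 0.693. The correlations were 0.716, 0.738 and 0.5, and 0.445, 0.449 and 0.449 in the simulations. That of PSS lay near the simulated one, while the covariance of PSS lay above its simulated value. Changes particular to a strain also lower a correlation, so nearness alone does not show an effect of shared controls. The 3 WT libraries cannot be split into parts of 2 each, so part of the excess may come from the shared controls.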

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

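The values in this part come from planned tests of the strains, while all tests of explanations were chosen only after the results were seen, the splits of the libraries included. The 3 counts of changes between rne(5p) and rne(WT) were singled out because a direct test found differences between the overexpressing strains, whatever their cause. They are 12 transcript features, 11 TSS and 265 PSS (limma, Benjamini-Hochberg). The transcript features are 6803r01 (log2 difference 6.25), ncr1230 (5.82), 6803r06 (5.37), ncl1700 (4.34), ncl0570 (2.81), sll1515 (1.34), slr5054 (1.32), sll0057 (1.26), slr0213-as (-0.83), ncl0690 (-0.89), sll0247-as2 (-1.50) and slr0744-as2 (-1.57). Of these 6803r01 and 6803r06 were called in every alternative run, while the other 10 calls were lost without rne(5p) replicate 1 or rne(5p) replicate 2, with adjusted p from 0.0857 to 0.550. The count of 12 fell to 2 without either of these libraries. The PSS at 2613286 on the plus strand of the chromosome was singled out because it rose in rne(WT), from 155 ± 8.87 to 284 ± 8.90, and fell in rne(5p), to 16.4 ± 1.47, with a log2 difference of -4.04. With a fold threshold of 2 it no longer counts as opposite, since its rise was by 0.88 on the log2 scale.

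For the calls between rne(WT) and WT, the 10 possible splits of the 6 libraries are too few for a share under 0.05. The real split gave 172 transcript features, 192 TSS and 82 PSS, and the highest of the others gave 0, 1 and 0. Of TSS, transcript features and PSS alike, 1 split, the real one, gave as many.

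On 4 plasmids all genes of one strand but the last tag were listed at 0 in all libraries. A strand without transcription is excluded, since 116 TSS on these strands passed the minimum mean. A candidate explanation is that a feature annotated across the whole strand made reads on every other gene ambiguous in counting. In 4 of 4 plasmids the 1 gene above 0 was the last tag, which the table also lists in 2 pieces at 0. The annotation used by the authors was not used here, so this stays a hypothesis, and no biological explanation was tested beyond transcription itself.

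The rRNA features were 41.4-fold and 76.1-fold higher in rne(5p) than in rne(WT). A general gain of stable RNA in the rne(5p) libraries was judged by tRNA features only. The 36 tRNA features had a median log2 difference of -0.156 and a highest of 1.21. These values argue against a gain shared by rRNA and tRNA features. The tRNA features took 0.0927 to 0.1185% of reads, and whether such reads follow the level of mature tRNA was not tested. Less complete removal of rRNA in the rne(5p) libraries and an effect of the strain itself cannot be told apart. Both rne(5p) libraries, and none of the other 6, held at least 0.349% rRNA reads, and the labels do not say how libraries were grouped for depletion.

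Features of pSYSA rose in rne(WT), and may have done so along the whole plasmid. The scaling of libraries as the cause is excluded, since the median log2 fold change of pSYSA TSS was 1.08 and that of chromosomal TSS -0.01. A gain along the whole plasmid has the values it needs, with 95.4% of pSYSA TSS above 0 on both strands, and plasmid DNA was not measured. For the PSS between 90108 and 92560 the values argue against that gain alone. In the PSS table, with no minimum mean, the ratio of their sum to that of the 241 other listed pSYSA PSS was 0.515 to 0.606 in the WT libraries and 2.86 to 3.5 in rne(WT), a log2 change of 2.55 (standard error 0.112), while the other sites rose by 1.20. The ratio was tried after a comparison of quartiles and a sum over the stretch, and the scaling of a library cancels in it. The stretch was set by the sites called higher in this same comparison, which can inflate the change. In the rne(5p) libraries, whose change against WT did not set the stretch, the ratio was 3.15 and 2.67. These libraries are no independent check. The stretch was set against the same WT libraries, among sites whose minimum mean included the rne(5p) values. Whether the level of CRISPR3 alone is enough stays open. The lower quartile of the tested sites, 2.96, lies near the upper bound for CRISPR3, 2.94, only 40 of 118 listed sites were tested, sites low in WT passed the minimum mean because they rose, and the tables were scaled separately.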

How the results depend on the processing

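All alternatives were planned except the lists without the 4 spanning plasmid features, added after seeing the data, which changed no list call. No call on a named feature or site and no list past its test turned direction, while 7 values of features that were not called and 14 of lists not past the test did. Of 124 calls among 148 values for named transcript features, 20 were lost and 4 gained with scaling by totals, 34 lost without a variance trend, 22 lost and 2 gained with only the strains compared, 12 lost without a filter, 3 lost with edgeR and 6 gained with DESeq2, while TMM and a pseudocount of 5 changed none. Leaving out single libraries lost 267 of 992 calls and gained 4. The cause was not tested, though fewer libraries and other numbers of features tested enter by construction.

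The replicate numbers did not pair the libraries, since deviations of same-numbered WT and rne(WT) libraries correlated at -0.268, -0.109 and -0.473 in transcripts, and below 0 in TSS and PSS. Those of same-numbered pairs with rne(5p) lay between -0.038 and 0.147. For differently numbered WT and rne(WT) libraries the deviations in transcripts correlated between -0.114 and 0.42, the highest for WT replicate 1 with rne(WT) replicate 3. A grouping of libraries that the numbers do not follow was not tested. With the number as a replicate block, 92, 4 and 248 transcript features were called in rne(WT) against WT, rne(5p) against rne(WT) and rne(5p) against WT, 7 and 286 TSS in the last 2, and 1 list in the second, where pSYSM had 0.0760. In rne(5p) against WT the nitrogen list passed (0.0119). With the block 79 of 124 named transcript calls held and 45 were lost.

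A fold threshold of 2 left 86 and 271 transcript features in rne(WT) against WT and rne(5p) against WT. Scaling by totals gave 315 and 1247, DESeq2 298 in the first, 117 in the second, and only the strains compared 104 and 66. Without a trend limma called 5 transcript features in the second comparison, 98 TSS in the first, 0 in the second (416 at an unadjusted p below 0.05, 27 by edgeR, 47 by DESeq2) and 251 in the last. For TSS of the second comparison a pseudocount of 5 gave 20, edgeR 27, DESeq2 47 and only the strains compared 38. For PSS a minimum mean of 50 left 22, 39 and 62, and no filter gave 490 and 625 in the second and last. With an estimated correlation camera passed 0, 0 and 0 lists, in place of 5, 2 and 4. At least 2-fold changes shared by both strains against WT numbered 51 and 21 transcript features (higher and lower), and 43 lower TSS. Opposite PSS fell from 1 to 0. Between the first and second comparison the opposite TSS fell from 1 to 0, and opposite PSS from 2 to 1 and from 4 to 2.

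Leaving out 1 library at a time gave 70 to 347, 2 to 97 and 113 to 764 transcript features, 89 to 249, 0 to 60 and 103 to 490 TSS, and 62 to 82, 114 to 321 and 170 to 366 PSS in the 3 comparisons, and 5 to 7, 2 to 5 and 4 to 7 lists. The lone rne(5p) library is then assumed to vary like the other strains. PSS had the fewest reads, 35774 to 66049 per library, and 972 of 6490 sites were tested. The planned base composition around PSS and comparison with the host transcript, with their alternatives (1 site per 10 nt, at least 2-fold, a mean of 50 in both tables), were not run, since no genome fitting the coordinates was used here.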

Other observations

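In rne(5p) against WT, further genes outside the lists that passed the set test changed. sll1514, the gene of the small heat shock protein HspA, rose 4.43-fold, from 514 ± 260 to 2098 ± 102, and slr1204, a protease gene of the HtrA family, rose 2.10-fold, from 787 ± 106 to 1674 ± 467. sll0856, which encodes the sigma factor SigH, rose 3.26-fold, from 237 ± 82.7 to 759 ± 215, while sll1689, for SigE, fell from 1894 ± 135 to 995 ± 147. With limma and Benjamini-Hochberg adjustment, adjusted p was 0.00344 for sll1514, 0.00687 for slr1204, 0.00594 for sll0856 and 0.00893 for sll1689. Without rne(5p) replicate 1 the calls on slr1204 (0.108), sll0856 (0.0966) and sll1689 (0.127) were lost. The bicarbonate transporter genes slr0040 and slr0041 rose 2.33-fold and 2.49-fold, to 1770 ± 573 and 1013 ± 299, and lost their calls without rne(5p) replicate 2 (0.0944 and 0.0821). Of the photosystem II genes ssl2598, which is psbH, fell from 4455 ± 141 to 2223 ± 210 (limma, Benjamini-Hochberg adjusted p = 0.00120), and of that list 1 rose and 5 fell of 28, 2 and 6 when adjusted over the list alone. NDH-1 held 3 genes that rose of 18, Rubisco and carboxysome 2 of 10, low-carbon uptake 3 that rose and 1 that fell of 15, chaperones 2 that rose of 14, high-light inducible proteins 2 of 4, RNases 3 of 14, pili 1 of 9 and pSYSX 1 of 13. Sigma factors held 1 that rose and 2 that fell of 9, and the phycobilisome, iron and pSYSG lists 1 each that fell. Adjusted over the list alone, the counts were 3 for NDH-1, 2 for carboxysome, 5 and 1 for low-carbon uptake, 3 for chaperones, 2 for high-light inducible proteins, 4 for RNases, 1 and 1 for pili, 3 for pSYSX, 3 for ATP synthase, of which none was called by limma over all genes, and 2 and 2 for sigma factors.

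Median, mean and camera direction differed in sign for a few lists. In rne(WT) against WT the median and mean log2 fold change were -0.01 and 0.11 for low-carbon uptake, and 0.05 and -0.01 for pili, 0.02 and -0.00 for NDH-1 and -0.00 and 0.07 for chlorophyll synthesis. In rne(5p) against rne(WT) they were -0.04 and 0.02 for the RNases. In rne(5p) against WT they were -0.02 and 0.12 for chaperones and 0.14 and -0.01 for iron, 0.00 and -0.02 for phosphate and -0.05 and 0.03 for sigma factors.

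The tests of this paragraph and the next were chosen only after the results were seen. RNase E has been reported to process the CRISPR3 transcript, and the PSS between 90108 and 92560 on pSYSA may recur with the period of its repeats. The best shared phase over periods of 60 to 85 nt was at 74.5 nt, with a permutation p of 0.00717 over 100000 resamples (one-sided). Resampled positions were drawn independently of each other, while sites close together are not independent, so this p can be too small. The stretch and the range of periods were chosen after the spacing was seen, no sequence was used here and no gene is attached to the sites. The sum over its 118 sites was added after the comparison of quartiles had been made, gave a log2 fold change of 3.75 (standard error 0.201) in rne(WT) against WT, and was not used to decide whether the level of CRISPR3, from a table scaled separately, is enough. The requirements that quartiles lie apart by more than the error of a site and that most listed sites be tested were also set after the values were seen.

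Sites higher and sites lower in rne(5p) than in rne(WT) lay together in 23 of 118 clusters with gaps of at most 200 nt. This closeness was not tested against chance. Where both occur, lower sites might lie downstream of higher ones, as a shift of the cleavage position would place them. The lower site was downstream in 46 of 95 pairs within 50 nt, 77 of 136 within 100 nt, 106 of 175 within 200 nt, 139 of 228 within 500 nt and 180 of 305 within 1000 nt. For 200 nt a permutation test over mirrored clusters gave p = 0.191 (adjusted p = 0.540 by Benjamini-Hochberg over 5 windows from 50 to 1000 nt, two-sided), and the adjusted values of the other windows were 0.930, 0.673, 0.540 and 0.563. The order stays open.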
